A study of Mus musculus with 20 samples.

How the data were processed

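The values are gene counts as deposited. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c to GRCm38/mm10 and counted with HTSeq, whose version is not given. Strand, annotation release and filters are not stated. RNA was extracted with Trizol as total RNA and sequenced from standard Illumina libraries. The table held 46603 Ensembl gene identifiers, of which 46005 were named from GENCODE M21 on GRCm38; the 598 without a name held 0.0759% of the counts. 20491 identifiers had no count in any library. Depth ran from 9985311 to 17462770 counts per library. HTSeq does not count reads that map to several places, so genes with close copies in the genome, such as H2-D1, H2-K1, Eno1, Ldha, Hspa8 and the Gzm and Bcl2a1 families, are counted in part. Without a stated strand, a gene that overlaps another on the opposite strand can carry counts of both.

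Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Scaling was by trimmed mean of M values, and filterByExpr with its default settings chose the genes. Each pool of libraries was fitted by itself: 8 melanoma libraries (12540 genes, 4 residual degrees of freedom), 12 T cell libraries (13432 genes, 6) and all 20 (14824 genes, 10). The common biological coefficient of variation was 2.69%, 2.79% and 2.77%. So small a spread can be technical, so p values in melanoma and in T cells need not cover the spread between separate cultures. Every comparison used edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at an adjusted p below 0.05. Printed standard errors are the log2 change divided by the square root of F. CPM are scaled by the same normalisation and are given as mean ± SD over the 2 libraries of a group. The deposit does not state whether the 2 libraries of a group are separate cultures. A gene with no counts in 1 group is given an at-least fold change against 3 counts over that group, and a gene with 1 to 3 counts is given the 95% exact binomial interval of the ratio.

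33 gene lists, with between 10 and 39 members, were fixed before the data were examined, together with 16 comparisons, the threshold of 0.05, the 2-fold threshold and the rule for naming genes. The lists cover the ISR, IRE1 and XBP1 targets, ER chaperones, ER-associated degradation, tRNA synthetases, calcium handling, apoptosis and survival, p53, SAGA, pigment, mitosis, replication, cholesterol, glycolysis, MHC class I, interferon, NF-kB, secreted cytokines, heat shock, NRF2, ribosome and T cell states. They also cover markers of other cells, and mitochondrial mRNA with haemoglobin. Lists with at least 5 tested members were tested by camera on voom values with a preset correlation of 0.01 and adjusted over the lists of a comparison. Members were counted as up or down by the adjustment over all genes, and again with the adjustment over the list alone. Where no second count is given for the list alone, both adjustments gave the same counts.

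The genes named are Sgf29 and Atp2a2 in every group and, per comparison of 2 groups, the 6 called genes that rose most and the 6 that fell most. These had no overlap between libraries and at least 10 CPM in the higher group, and gene-model symbols were left out. Comparisons of effects and of TG with KO name 4 each way, and the overlap rule does not apply to comparisons of effects. From each list up to 4 called members with the largest change were eligible, and a fixed panel (Atp2a3, Hspa5, Ddit3, Trib3, Chac1, Dnajb9, Herpud1, Xbp1, Atf4, Bbc3, Bcl2l11, Mitf, Tyr, Pmel, Ifng, Gzmb, Prf1, Il2, Il2ra, Pdcd1, Nr4a1, Rcan1, Tcf7 and others) completes them. The comparison of activated with labelled resting Atp2a2 KO libraries, and the fits without the labelled resting libraries, were added after the data had been examined.

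Alternatives were DESeq2 1.42.0, relative log expression scaling, no filter, a filter of 5 CPM in 2 libraries, a term for replicate number, fits of only the compared groups, each library left out, camera with an estimated correlation, and fry. Correlations between comparisons that share controls were set against 20 simulations of unchanged groups. The pipeline was tested on simulated data with the observed means, depths and dispersions, 50 genes per fold size. For TG in control melanoma 12360 genes were fitted and edgeR recovered 68%, 88% and 94% of the changes of 1.5, 2 and 4-fold, with 9 false calls; DESeq2 recovered 62%, 84% and 82% with 0 false calls. For TG in resting T cells 13153 genes were fitted and edgeR recovered 70%, 74% and 94% with 15 false calls; DESeq2 recovered 62%, 66% and 90% with 4. For the smallest simulated change, below 1.5-fold, edgeR recovered 48% in melanoma and 64% in T cells, and DESeq2 26% and 42%. Camera called 0 of 32 unchanged lists in each, and the raised list of 25 genes at adjusted p = 2.5e-76 and 5.3e-60. The simulated genes were drawn independently and the lists at random, so this does not test the preset correlation on lists of co-regulated genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.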

Results

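Gene counts of total RNA were measured by sequencing in 20 mouse libraries, 2 for each of 10 groups. 8 libraries came from B16F10 melanoma cells with a control guide or a Ccdc101 knockout (KO), each given thapsigargin (TG, an inhibitor of the SERCA calcium pumps, 50 ng/mL for 8 hours) or dimethyl sulfoxide vehicle. 12 libraries came from OT-I/Cas9 CD8 T cells. Control-guide T cells were resting or activated with anti-CD3 (2.5 µg/mL, 24 hours), each with TG or vehicle, and Atp2a2 KO T cells with vehicle were labelled resting or activated. Depth was 16204005 and 13078825 counts in the 2 libraries of control melanoma with vehicle and 10663938 and 10934719 with TG. Ccdc101 KO melanoma had 12186117 and 10874550 counts with vehicle and 11612190 and 13991510 with TG. Resting control T cells had 12799661 and 11028101 counts with vehicle and 12522986 and 11022274 with TG. Activated control T cells had 17462770 and 13521582 counts with vehicle and 11577923 and 12877673 with TG. The Atp2a2 KO libraries had 10542364 and 9985311 counts (labelled resting) and 17391798 and 12329629 (activated).

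**Figure D1:**
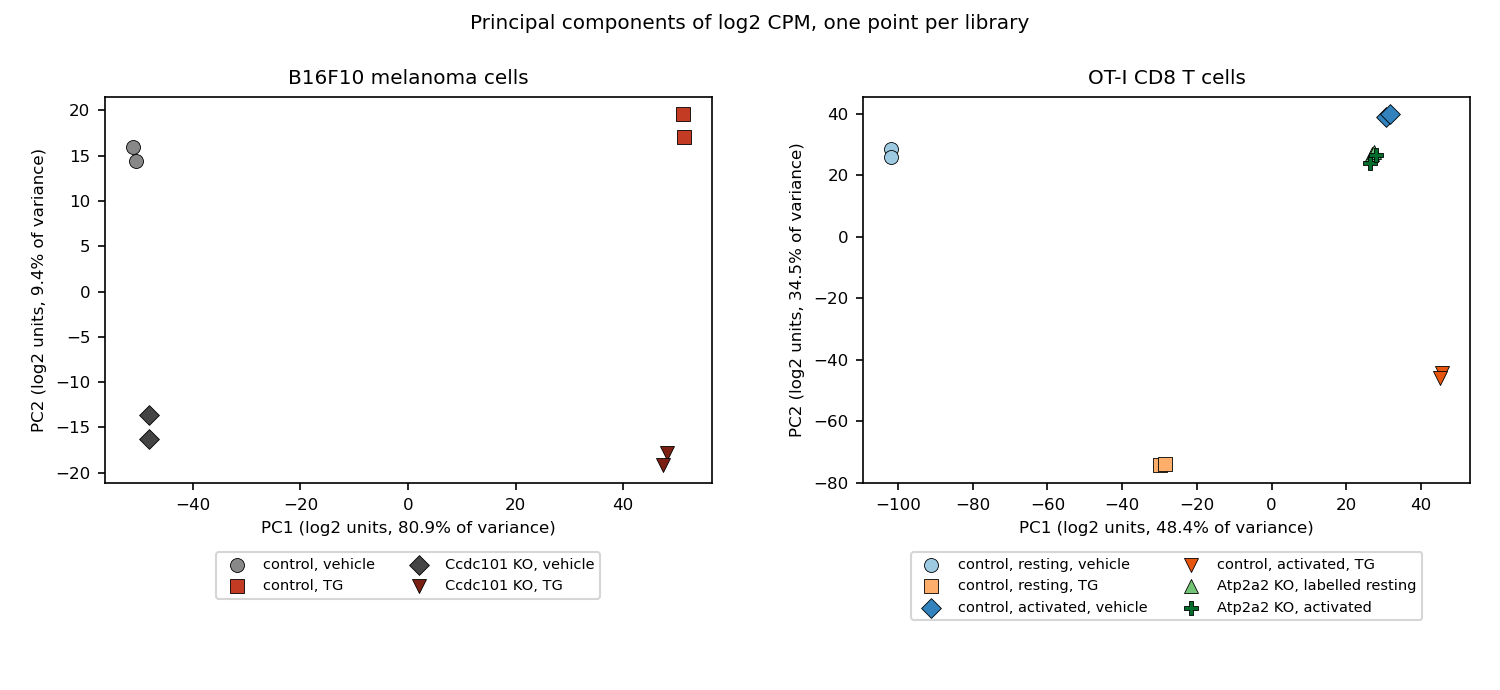
Principal components of the B16F10 libraries (left, 80.9% and 9.4% of the variance on the axes) and of the T cell libraries (right, 48.4% and 34.5%), 1 point per library and 1 colour per group. The 4 Atp2a2 KO points lie together near the activated control T cells, whatever their label.

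The targeted genes were looked at first, in every group. Ccdc101 is now named Sgf29 (chr 7:126649309-126672925 on GRCm38) and encodes a subunit of the SAGA histone acetyltransferase complex. Its mRNA was 28.8 ± 0.99 counts-per-million (CPM, mean ± SD, n = 2 throughout) in control melanoma and 19.2 ± 0.6 in the KO with vehicle (log2 change -0.59 ± 0.085 SE, adjusted p = 6.6e-07). With TG it was 35.8 ± 0.31 in the control and 26.0 ± 1.5 in the KO (-0.46 ± 0.081, adjusted p = 1.8e-05). Atp2a2 (chr 5:122453513-122502225) encodes SERCA2, the pump that TG blocks. In activated T cells Atp2a2 mRNA was 675 ± 16 CPM in the control and 435 ± 1.3 in the KO (-0.63 ± 0.034, adjusted p = 9.2e-23). In resting T cells it was 225 ± 0.37 CPM in the control and 453 ± 2.2 in the libraries labelled resting Atp2a2 KO. This rise of 1.01 ± 0.037 (adjusted p = 9.9e-32) is unlike the fall in activated KO cells. Yet 453 CPM lay below the activated control and near the activated KO, so the rise does not by itself speak against the KO. With TG Atp2a2 mRNA was 364 ± 4.7 CPM in resting and 600 ± 5.4 in activated control T cells. A cut by a guide need not lower the mRNA, and mRNA does not measure the protein, so these values do not show how complete either KO was.

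**Figure D2:**
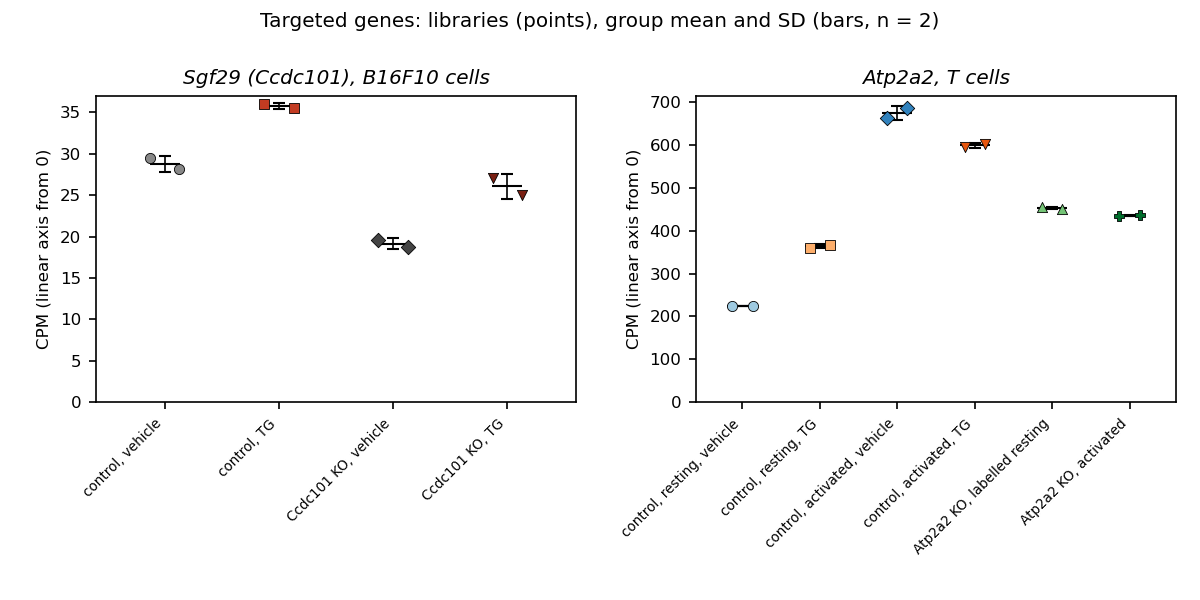
CPM of Sgf29 in the 4 melanoma groups and of Atp2a2 in the 6 T cell groups on linear axes, with points for libraries and bars for mean and SD (n = 2). Atp2a2 was 453 CPM in the libraries labelled resting Atp2a2 KO against 225 in resting controls.

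The first question was what 8 hours of TG changed in control melanoma cells. Atp2a3, which encodes the SERCA3 pump, rose from 0.0375 ± 0.053 to 31.2 ± 3.5 CPM. With 1 count in the vehicle libraries, the 95% counting interval of the ratio was 166 to 36700. Pdzd7 rose from 0.105 to 10.4 ± 0.6 (interval 34.9 to 505), Akr1b7 from 0.159 ± 0.12 to 14 ± 1.8, Isg20 from 0.204 to 11.1 ± 0.72 and Cftr from 0.52 to 20.1 ± 0.22. The stress gene Nupr1 rose from 5.63 ± 0.31 to 244 ± 0.35 (5.44 ± 0.068, adjusted p = 4.1e-43). Kank4 fell from 87.8 ± 4.2 to 2.16 ± 0.64 CPM, Angptl2 from 175 ± 6.8 to 10.4 ± 0.9, Xkr5 from 12.4 to 0.478, Paqr7 from 27.9 to 1.64 and Map2k6 from 18.2 to 1.1. Tk1, the thymidine kinase of S phase, fell from 119 ± 0.87 to 4.66 ± 0.14 (-4.67 ± 0.094, adjusted p = 1.4e-35). Fgf21 had no counts with vehicle and 1.68 CPM with TG, at least 16.7-fold when 3 counts over the group are taken as the floor. The pump's own gene Atp2a2 rose from 767 ± 4.0 to 1870 ± 18 CPM (1.28 ± 0.027, adjusted p = 7.2e-35), while Itpr1, which encodes a calcium release channel, fell from 255 ± 20 to 63.9 ± 7.2.

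Genes of the endoplasmic reticulum (ER) stress response rose together with TG. Among ATF4 and CHOP targets of the integrated stress response (ISR), 37 of 38 rose and 0 fell. Ppp1r15a went from 18.5 ± 1.2 to 598 ± 2.7 CPM, Atf3 from 5.26 ± 0.31 to 141 ± 5.2 and Trib3 from 27.9 ± 0.77 to 701 ± 2.2. Ddit3, which encodes CHOP, rose from 33.9 ± 4.2 to 892 ± 13 (4.73 ± 0.052, adjusted p = 1.8e-32), Chac1 from 34.5 ± 0.61 to 248 ± 13 and Atf4 itself from 401 ± 11 to 1440 ± 0.43. All 27 tested IRE1 and XBP1 targets rose, among them Dnajb9 from 11.4 ± 0.77 to 192 ± 0.95 and Xbp1 from 122 ± 1.9 to 418 ± 3.2. The ER chaperone Hspa5 rose from 1710 ± 3.7 to 17300 ± 340 CPM (3.34 ± 0.022, adjusted p = 2.8e-53), Creld2 from 121 ± 1.5 to 1670 ± 25 and Pdia4 from 626 ± 4.3 to 4920 ± 32. In all, 18 of 20 ER chaperones rose and 1 fell. Of 19 genes of ER-associated degradation 18 rose and 0 fell, led by Herpud1, from 125 ± 0.32 to 1920 ± 48 CPM, and Sel1l, from 179 ± 0.51 to 1960 ± 8.8. Aminoacyl-tRNA synthetases followed with 16 of 20 up and 2 down, such as Wars (220 ± 5.4 to 845 ± 8.6) and Nars (363 ± 5.6 to 1140 ± 11).

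Proliferation genes went the other way in the same cells. All 24 mitotic genes fell, for example Aurkb from 171 ± 3.8 to 48.6 ± 2.1 CPM and Ccna2 from 374 ± 6.8 to 110 ± 2.3. All 26 replication genes fell, for example Lig1 from 258 ± 4.4 to 48.9 ± 1.4 and Mcm6 from 576 ± 7.5 to 114 ± 1.2. 15 of 19 pigment genes fell and 3 rose. The receptor gene Mc1r fell from 197 ± 2.4 to 54.1 ± 2.8, Mlph from 506 ± 8.4 to 209 ± 6.6. The melanocyte regulator Mitf fell from 500 ± 0.3 to 343 ± 0.087, Tyr from 213 ± 1.6 to 154 ± 2.4 and Pmel from 3160 ± 48 to 2250 ± 73. Glycolysis genes fell in 16 of 20 and rose in 1 (Ldha 1540 ± 21 to 724 ± 1.4), and cytosolic heat shock genes fell in 10 of 12 and rose in 1 (Hspa8 1920 ± 51 to 531 ± 16). Camera with its preset correlation called these lists at adjusted p = 5.2e-21 (ISR), 1.4e-17 (IRE1 and XBP1), 1.6e-12 (ER chaperones), 5.8e-11 (ER-associated degradation), 1.3e-06 (tRNA synthetases), 1.6e-13 (mitotic), 3.8e-15 (replication), 0.00038 (pigment), 7.3e-05 (glycolysis) and 0.00024 (heat shock). In the same order, adjusted p = 0.057, 0.014, 0.057, 0.016, 0.17, 0.014, 0.057, 0.16, 0.29 and 0.29 with an estimated correlation.

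Genes of cell death did not move as a group in TG-treated melanoma. Of 13 pro-apoptotic BCL2-family and related genes 2 rose and 6 fell (camera adjusted p = 0.32). Bbc3 rose from 5.74 ± 1.3 to 10.8 ± 0.22 CPM, whereas Bcl2l11 fell from 6.43 ± 0.15 to 4.17 ± 0.28. Of 9 survival genes 4 rose and 4 fell (adjusted p = 0.64), with Cflar up from 86.7 ± 1.9 to 250 ± 2.1, Bcl2 up from 35.1 ± 0.89 to 79.1 ± 3.2 and Birc5 down from 162 ± 5.1 to 57.4 ± 2.2. Of 18 p53 targets 11 rose and 4 fell (adjusted p = 0.085), with Gadd45a up from 4.2 to 74.4 ± 1.1. In all, 4476 genes were higher and 4526 lower of 12540 tested, 1344 and 1309 of them by at least 2-fold. The list counts were the same when adjusted over the list alone. All p values here rest on the spread between the 2 libraries of each group. That spread is pooled over the 4 melanoma groups and moderated across genes, and it can be technical.

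The second question was what TG changed in the Ccdc101 KO melanoma cells. Akr1b7 rose from 0.0828 to 23.2 ± 1 CPM (counting interval of the ratio 77.4 to 2320). Cd74, the MHC class II invariant chain, rose from 0.127 to 32.6 ± 4.0 (89.2 to 1270), Atp2a3 from 0.258 ± 0.25 to 36.4 ± 4.1, P2rx3 from 0.292 to 16.4, Isg20 from 0.287 to 15.8 and Apobr from 0.375 to 17.4. Rab17 fell from 11 to 0.273, Kank4 from 90.7 ± 1.5 to 2.7 ± 0.047, Angptl2 from 138 ± 5.0 to 5.13 ± 0.27, Mest from 28.2 to 2.19 and Tk1 from 120 ± 1.4 to 6.58 ± 1.6. Hspa5 rose from 1640 ± 3.7 to 18800 ± 86 CPM (3.52 ± 0.022), Ddit3 from 23.6 ± 2.3 to 699 ± 6.8, Trib3 from 24.5 ± 3.1 to 722 ± 17 and Herpud1 from 94.8 ± 4.5 to 1810 ± 41. Atp2a2 rose from 730 ± 5.3 to 1950 ± 31 and Bbc3 from 3.32 ± 0.39 to 9.11 ± 1.4, while Mitf fell from 454 ± 8.0 to 189 ± 4.4 and Mc1r from 153 ± 0.98 to 35 ± 0.27.

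The same gene groups moved in the KO cells. ISR genes rose in 37 of 38, IRE1 and XBP1 targets in 27 of 27, ER chaperones in 19 of 20 with 1 down, and ER-associated degradation genes in 19 of 19. Mitotic genes fell in 23 of 24, replication genes in 25 of 26 and pigment genes in 16 of 19 with 2 up. Camera gave adjusted p = 7e-23, 1.7e-19, 3.9e-15, 4.7e-12, 1.9e-12, 3.9e-15 and 1e-05 for them, and in that order adjusted p = 0.048, 0.013, 0.048, 0.013, 0.013, 0.055 and 0.087 with an estimated correlation. NF-kB genes rose in 9 of 10 and 0 fell, for example Relb from 8.78 to 63.3 CPM (adjusted p = 0.0039; adjusted p = 0.13 with an estimated correlation), and p53 targets in 13 of 18 with 4 down (adjusted p = 0.0068; adjusted p = 0.1 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 21 and fell in 3, for example Fdps from 28.5 ± 0.079 to 82 ± 4 (adjusted p = 0.0013; adjusted p = 0.21 with an estimated correlation). In all, 4271 genes were higher and 4546 lower of 12540, 1084 and 1276 by at least 2-fold, against 3634 and 3625 with DESeq2. Across the 12540 genes the log2 changes with TG in control and KO cells had Pearson r = 0.914 and Spearman rho = 0.901, and r = 0.393 with no filter on low counts. 3740 genes were higher in both (1520 if the calls were independent), 3881 lower in both (1640), and 47 and 42 were called in opposite directions. Genes are not independent replicates, so these coefficients carry no p value.

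The third question was how Ccdc101 KO cells differed from control melanoma without TG. Lgals3, which encodes galectin-3, rose from 4.13 ± 0.42 to 32.6 ± 1.5 CPM (2.99 ± 0.11, adjusted p = 1.6e-23), S100a6 from 3.32 ± 0.029 to 17.7 ± 0.023, Tns1 from 10.5 ± 1.3 to 42.2 ± 0.66, Rassf4 from 5.66 to 21.6 and Slc27a1 from 5.35 to 17.5. Ngfr, a neural crest receptor gene, rose from 4.79 ± 0.24 to 16.3 ± 0.83. Dpysl3 fell from 16.9 ± 0.71 to 4.88 ± 0.71, Adam23 from 14 to 4.48, Abca12 from 24.6 to 8.36, Lmo1 from 30.6 ± 2.7 to 11.8 ± 0.079, Sytl2 from 42.2 to 18.2 and Hapln1 from 25.2 to 11.1. Pigment genes fell in 18 of 19 and none rose. Pmel went from 3160 ± 48 to 2100 ± 70 (-0.59 ± 0.027, adjusted p = 2.3e-20), Tyr from 213 ± 1.6 to 167 ± 1.3, Mitf from 500 ± 0.3 to 454 ± 8.0 and Trpm1 from 7.34 to 2.97. The antigen presentation regulator Nlrc5 rose from 0.686 ± 0.2 to 5.73 ± 2.2 and H2-D1 from 27.9 ± 0.42 to 40.5 ± 4.8. MHC class I genes rose in 6 of 9, interferon-stimulated genes in 6 of 17 (8 when adjusted over the list alone) and NF-kB genes in 6 of 10, and none of these fell.

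Stress genes were lower in the KO with vehicle, by small amounts. Ddit3 was 23.6 ± 2.3 CPM against 33.9 ± 4.2, Herpud1 94.8 ± 4.5 against 125 ± 0.32 and Hspa5 1640 ± 3.7 against 1710 ± 3.7 (-0.06, adjusted p = 0.035), whereas Atf3 rose from 5.26 ± 0.31 to 11.3. Of 20 ER chaperones 11 fell and 0 rose (12 and 1 alone), of 38 ISR genes 16 fell and 4 rose (18 and 4 alone), and of 23 SAGA subunits 3 rose and 3 fell (camera adjusted p = 0.87). Camera called pigment at adjusted p = 1e-20, MHC class I at 0.001, interferon at 0.0094, NF-kB at 0.0013, ER chaperones at 0.00045 and ISR at 0.0012. In that order, adjusted p = 0.044, 0.17, 0.17, 0.2, 0.2 and 0.32 with an estimated correlation. In all, 1550 genes were higher and 1668 lower of 12540, 186 and 41 by at least 2-fold. The split of the calls depends on the tool: 48.2% were higher by edgeR, 42.1% with relative log expression scaling and 37.2% by DESeq2, which called 561 higher and 947 lower. How the control and KO lines were derived is not stated beyond the guide, so any other difference between the lines would be counted as KO.

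The fourth question was how the KO differed from the control when both had TG. Cdsn rose from 5.61 ± 0.12 to 19.6 ± 0.81 CPM, Cd74 from 9.88 ± 0.54 to 32.6 ± 4.0 (1.72 ± 0.12), Prss23 from 4.03 to 12.3, and Ngfr from 4.86 ± 1.4 to 14.1 ± 0.53. The inflammatory caspase gene Casp4 rose from 3.79 to 10.3 and L1cam from 12.5 ± 2.3 to 33.4 ± 0.42. Kcnq1ot1 fell from 22.5 to 6.13, Nr4a3 from 219 ± 20 to 63.7 ± 1.0, Slc18a1 from 10.7 to 3.46, Bace2 from 46.6 ± 3.5 to 15.1 ± 0.3, Pde10a from 47 ± 0.88 to 15.7 ± 1.4 and Pde1c from 10.9 to 4.04. All 19 pigment genes fell, with Mitf from 343 ± 0.087 to 189 ± 4.4 (-0.86 ± 0.036, adjusted p = 2.7e-22), Tyr from 154 ± 2.4 to 91.1 ± 1.9 and Pmel from 2250 ± 73 to 1400 ± 4.1. Mitotic genes rose in 16 of 24 and 0 fell (20 up and 1 down alone), such as Aurkb from 48.6 ± 2.1 to 69.1 ± 1.8 and Ccnb1 from 48.1 ± 0.73 to 62.9 ± 0.1. ER chaperones rose in 11 of 20 and 0 fell (12 and 2 alone), with Hspa5 from 17300 ± 340 to 18800 ± 86 and Hsp90b1 from 12400 ± 87 to 14200 ± 150. NRF2 targets rose in 10 of 14 and 1 fell (11 and 1 alone), with Hmox1 from 642 ± 16 to 957 ± 1.

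With camera, KO against control under TG had adjusted p = 5.8e-24 for pigment, 2.7e-06 for the mitotic genes, 4.3e-07 for ER chaperones and 2.7e-06 for NRF2 targets. In that order, adjusted p = 0.036, 0.066, 0.13 and 0.1 with an estimated correlation. In all, 2078 genes were higher and 1878 lower, 105 and 182 by at least 2-fold. The balance depends on the tool, since DESeq2 called 1032 higher and 1078 lower, and leaving out 1 KO library gave as few as 2615 calls.

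Whether the TG effect itself differed between KO and control melanoma was tested as an interaction. Mitf fell more in the KO (difference of log2 changes -0.72 ± 0.049, adjusted p = 1.9e-14), as did Met (-0.56 ± 0.047), Sox10 (-0.52 ± 0.05) and Tyr (-0.41 ± 0.06). Nme4 (1.00 ± 0.18), Tsku (0.92 ± 0.17), Als2cl (0.90) and Rab3il1 (0.88) had the largest positive differences among called genes with at least 10 CPM in the highest group, gene models left out. Slc18a1 (-2.02 ± 0.55), Lgals3 (-1.99 ± 0.13), Ppm1e (-1.91) and Id1 (-1.91) had the largest negative ones by the same rule. Lgals3 rose in both: TG took it from 4.13 ± 0.42 to 70.0 ± 2 CPM in the control and from 32.6 ± 1.5 to 140 ± 3.4 in the KO. Hspa5 (0.17 ± 0.029) and Pdia4 (0.37 ± 0.035) rose more in the KO. Herpud1 (0.32) also had a larger log2 rise there, but from a lower start. It was 94.8 ± 4.5 CPM in the KO against 125 ± 0.32 in the control with vehicle, and 1810 ± 41 against 1920 ± 48 with TG. Aurkb (0.52) fell less in the KO, from 170 ± 3.8 to 69.1 ± 1.8, than in the control, from 171 ± 3.8 to 48.6 ± 2.1. The difference was not called for Ddit3 (0.16, adjusted p = 0.26), Pmel (-0.09, adjusted p = 0.11) or Atp2a3 (-2.35, adjusted p = 0.24). ER chaperones had 16 of 20 positive and 0 negative (17 and 1 alone), and mitotic genes 13 of 24 and 0 (19 and 0 alone). Cholesterol genes had 9 of 21 and 0 (12 and 0 alone) and pigment genes 0 positive and 9 negative of 19 (1 and 12 alone). Camera gave adjusted p = 1.8e-14, 7.4e-10, 1.2e-07 and 7.4e-10, and in that order adjusted p = 0.074, 0.051, 0.099 and 0.074 with an estimated correlation. In all, 898 differences were positive and 746 negative, 9 and 105 of them by at least 2-fold. 54.6% were positive by edgeR, 60.2% with relative log expression scaling and 66.6% by DESeq2, which called 442 and 222. Leaving out 1 KO library gave as few as 1090 calls.

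**Figure D3:**
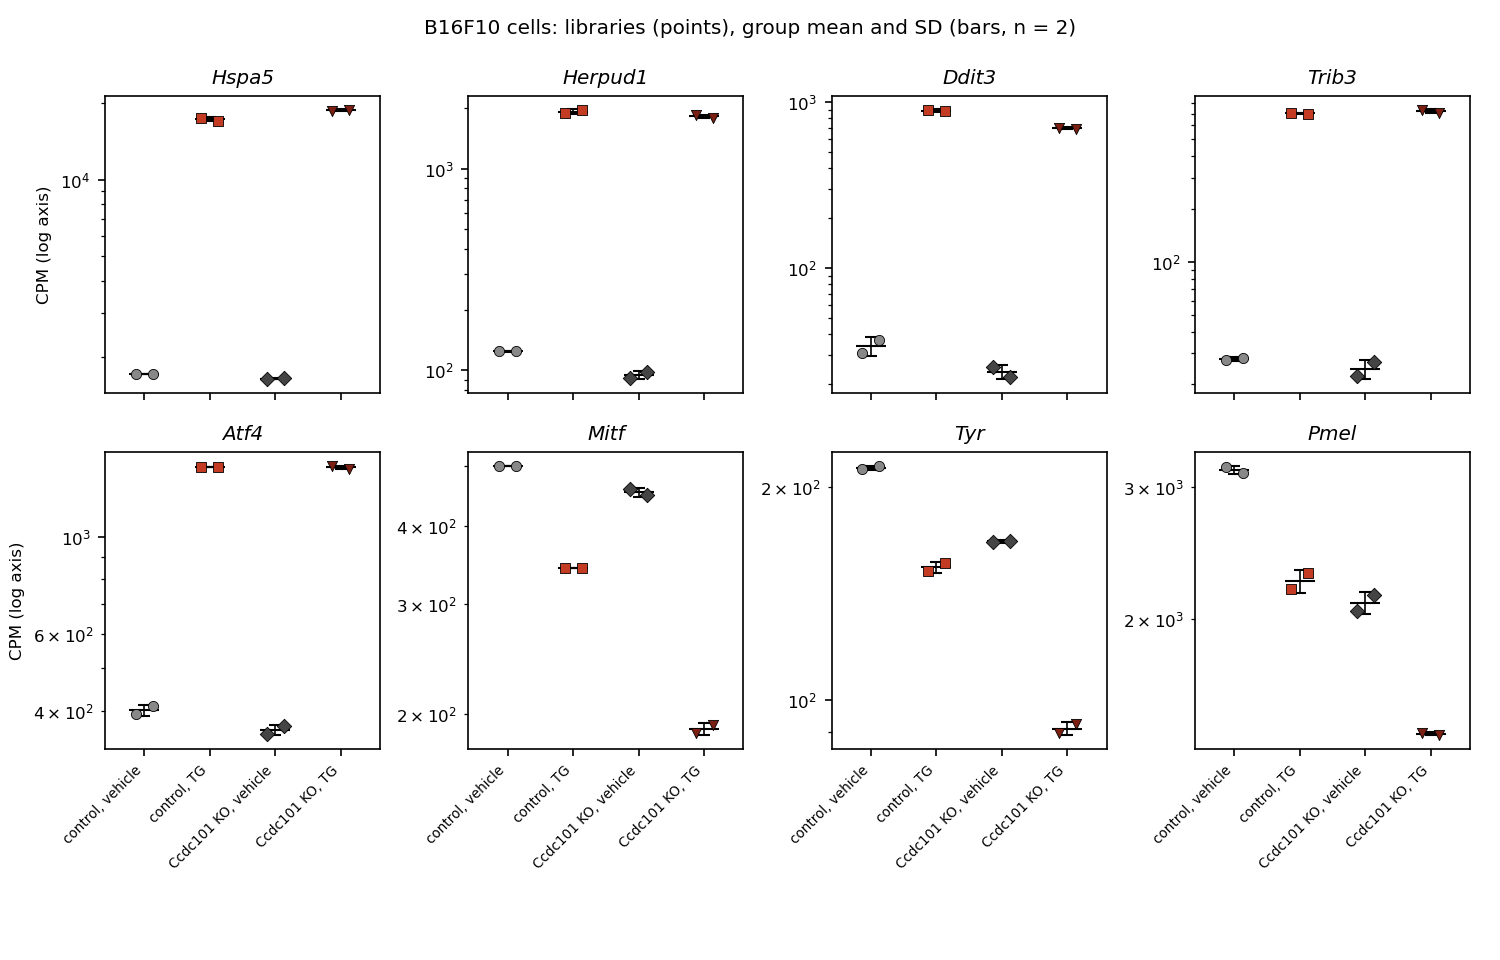
CPM of Hspa5, Herpud1, Ddit3, Trib3, Atf4, Mitf, Tyr and Pmel in the 4 melanoma groups on log axes, with points for libraries and bars for mean and SD (n = 2). Hspa5 was 1710 CPM with vehicle and 17300 with TG in the control, and Mitf 343 in control and 189 in KO cells with TG.

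In the T cells, the first question was what activation changed in control cells with vehicle. The resting cells already expressed effector genes, with Gzmb at 10500 ± 320 and Il2ra at 1320 ± 34 CPM, so changes are relative to such cells. Ifng, which encodes interferon gamma, rose from 9.39 ± 0.55 in resting to 4790 ± 110 CPM in activated cells (adjusted p = 4.3e-71), and Ccl3 from 2.85 ± 1.2 to 1420 ± 30. Xcl1 rose from 2.37 ± 0.96 to 1110 ± 4.6 and the costimulatory receptor gene Tnfrsf4 from 13.7 to 403 ± 9.2. Il22 (46.9 ± 3.9 CPM), Il2 (16 ± 0.32), Stra6 (13.7), Il6 (12.9), Slc1a2 (12) and Il21 (11.5) had no counts in resting cells. Their rises were at least 367-, 124-, 106-, 99.9-, 93.5- and 88.4-fold against 3 counts over the group. Gzmb, which encodes granzyme B, rose from 10500 ± 320 to 20100 ± 370. Prf1, which encodes perforin, rose from 311 ± 11 to 948 ± 2.3 and Il2ra from 1320 ± 34 to 5670 ± 100. Ifi208 fell from 81.4 ± 0.5 to 0.71 ± 0.15, Ifi213 from 43.1 to 0.585, Calhm6 from 34.1 to 0.498, and Cd7 from 35 to 0.62. Tcf7, which encodes the TCF1 factor of naive and memory cells, fell from 209 ± 0.45 to 34.6 ± 0.2. Atp2a2 rose from 225 ± 0.37 to 675 ± 16 (1.58 ± 0.036, adjusted p = 1.2e-41) while Atp2a3 fell from 469 ± 3.1 to 79.8 ± 1.4, and Bcl2l11 fell from 193 ± 0.83 to 23.6 ± 0.43.

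NF-kB genes rose in 18 of 18 with activation, such as Nfkb2 from 102 ± 5.6 to 522 ± 13 CPM, cholesterol genes in 19 of 21 and effector genes in 18 of 24 with 6 down. Naive and memory genes fell in 19 of 21 with 2 up, interferon-stimulated genes in 19 of 24 with 4 up (Gbp2 from 410 to 48), and mitotic genes in 24 of 24 (Ccnb2 from 119 to 33.5). By camera these lists had adjusted p = 3.5e-09, 9.7e-07, 0.00017, 2.5e-05, 5.8e-05 and 3.5e-09, and in that order adjusted p = 0.028, 0.12, 0.19, 0.028, 0.12 and 0.028 with an estimated correlation. In all, 4740 genes were higher and 5250 lower of 13432, 1639 and 2116 by at least 2-fold. The mitotic genes fell from a level that resting cells already held, such as 119 CPM for Ccnb2. As in melanoma, p values within T cells rest on the spread between the 2 libraries of each group. That spread is pooled over the 6 T cell groups and can be technical.

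The next question was what TG changed in resting control T cells. Ifng rose from 9.39 ± 0.55 to 1490 ± 14 CPM (7.31 ± 0.051, adjusted p = 1.7e-66), and Xcl1 from 2.37 ± 0.96 to 688 ± 16 (8.21 ± 0.075). Ccl3 rose from 2.85 ± 1.2 to 369 ± 12, Tnfsf14 from 9.9 ± 0.36 to 526 ± 11 and the Notch ligand gene Jag1 from 0.455 ± 0.53 to 132 ± 2.7. Rbpms2 reached 26.4 ± 1.4 CPM from no counts, at least 206-fold against 3 counts over the group. Bdh2 rose from 0.0461 to 17.6 ± 2.8 (counting interval of the ratio 72.5 to 16100), Lctl from 0.0402 to 17 ± 2.5 (71 to 15700) and Cd24a from 0.132 to 42.7 ± 0.47 (113 to 1610). Esm1 fell from 20 ± 1.1 to 0.242, Klhl30 from 16.3 to 0.242, Col6a1 from 17.6 to 0.274, Tgm2 from 125 ± 1.2 to 2.22 ± 1.3, Igfbp4 from 142 ± 0.22 to 2.63 ± 1.2 and Ifit1bl1 from 16.6 to 0.403. Granzyme and perforin genes did not follow Ifng. Gzmb fell from 10500 ± 320 to 1500 ± 13 (-2.80 ± 0.031, adjusted p = 1.9e-56) and Prf1 from 311 ± 11 to 98.9 ± 3.4, while Il2ra stayed at 1320 ± 6.7 against 1320 ± 34 (adjusted p = 0.98).

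Early response genes of the T cell receptor and NFAT targets rose in 18 of 25 and fell in 5 with TG in resting cells. Nr4a3 went from 23.4 ± 0.018 to 1270 ± 26 CPM, Nr4a1 from 3.26 ± 0.74 to 96.1 ± 3.5, Egr2 from 1.93 to 110 ± 2 and Rcan1, a calcineurin feedback gene, from 7.35 ± 1.1 to 54 ± 2.1. Inhibitory receptor genes rose in 9 of 13 and fell in 4, with Lag3 from 137 ± 2.2 to 1030 ± 20, Pdcd1 from 23.7 ± 0.85 to 159 ± 5.5 and Cd244a down from 57.6 to 7.57. Naive and memory genes fell in 16 of 21 and rose in 4, with Tcf7 from 209 ± 0.45 to 82.7 ± 3.2 and S1pr1 from 49.7 to 4.27. Activation surface markers and costimulatory receptor genes rose in 12 of 19 and fell in 4, and effector genes rose in 9 of 24 and fell in 13 (camera adjusted p = 0.23). ISR genes rose in 34 of 36 and fell in 1 (Ddit3 17.8 ± 1.6 to 71.6 ± 3.8, Trib3 57.3 ± 0.37 to 200 ± 8.4). ER chaperones rose in 16 of 20 and fell in 1 (Hspa5 712 ± 18 to 2020 ± 45), and IRE1 and XBP1 targets rose in 25 of 27 and fell in 1. All 24 mitotic, 26 replication and 21 cholesterol genes fell, such as Ccna2 from 276 ± 3 to 74 ± 0.034, Rrm2 from 336 ± 0.057 to 59.4 ± 1.7 and Lss from 155 ± 3.3 to 28.9 ± 3.5.

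Of 25 calcium-handling genes 10 rose and 13 fell in resting cells with TG (adjusted p = 0.48). Orai1, the store-operated channel, went from 19.7 ± 1.8 to 104 ± 1.5 CPM, Atp2a2 from 225 ± 0.37 to 364 ± 4.7 (0.69 ± 0.037) and Atp2a3 from 469 ± 3.1 down to 127 ± 7.2. Of 17 pro-apoptotic genes 6 rose and 10 fell (adjusted p = 0.61), with Bcl2l11 up from 193 ± 0.83 to 216 ± 9.2 and Bbc3 down from 38.1 to 27.7. Camera gave adjusted p = 1.6e-05 for the receptor and NFAT list, 0.0018 for inhibitory, 8.8e-05 for naive and memory, 0.0088 for activation markers, 6.2e-17 for ISR, 8.7e-06 for ER chaperones, 5.4e-09 for IRE1 and XBP1, 3.3e-15 for mitotic, 7.3e-14 for replication and 3.4e-12 for cholesterol. In that order, adjusted p = 0.091, 0.061, 0.04, 0.34, 0.059, 0.28, 0.091, 0.016, 0.017 and 0.059 with an estimated correlation. In all, 4574 genes were higher and 4726 lower of 13432, 1474 and 1751 by at least 2-fold. Of markers of other cells, 3 of 3 fell for B cells, 5 of 6 for myeloid cells and 2 of 3 for fibroblasts and endothelium, while CD4 and NK cell markers rose in 4 and fell in 1 of 6 (camera adjusted p = 0.36). All 6 tested mitochondrial mRNAs fell (camera adjusted p = 0.077).

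The same question was asked for TG in activated control T cells. Fam171b rose from 1.16 ± 0.25 to 77.1 ± 3.2 CPM, and the mitochondrial folate enzyme gene Aldh1l2 from 4.09 ± 0.1 to 117 ± 8.3. Vwa5a rose from 35.8 ± 0.89 to 744 ± 11, Cox6a2 from 0.373 to 14 ± 0.58, Bdh2 from 0.757 to 17.4 and Grb10 from 0.582 to 12.8. Tnfrsf8, which encodes CD30, fell from 731 ± 7.7 to 21.4 ± 1.8 (-5.09), and Epas1 from 88.2 ± 0.61 to 3.52 ± 0.53. Tgm2 fell from 71.4 ± 0.32 to 1.39 ± 0.45, Selp from 30.3 to 0.57, Tcrg-C1 from 16.8 to 0.2 and Fgr from 16.6 to 0.642. Ifng rose from 4790 ± 110 to 10300 ± 130 (1.10 ± 0.031, adjusted p = 6.1e-37) and Il2 from 16 ± 0.32 to 30.3 ± 1.2. Gzmb fell from 20100 ± 370 to 6000 ± 6.2 (-1.74 ± 0.03, adjusted p = 5e-47), Prf1 from 948 ± 2.3 to 270 ± 1.9, Il2ra from 5670 ± 100 to 2850 ± 26, Lta from 253 ± 1.7 to 19.1 ± 0.89 and Il10 from 306 ± 3.3 to 44.3 ± 0.78. Pdcd1 rose from 40.7 ± 0.066 to 97.4 ± 1.5 and Lag3 from 384 ± 7.4 to 1120 ± 42. Bcl2l11 rose from 23.6 ± 0.43 to 57.6 ± 0.3 and Bbc3 from 11.1 ± 2.1 to 27.3 ± 1.6, while Bcl2l1 fell from 307 to 134.

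Effector genes fell in 17 of 24 and rose in 6 in activated cells with TG, and inhibitory genes rose in 10 of 13 and fell in 2. ISR genes rose in 34 of 36 and fell in 2 (Ddit3 9.87 ± 1.1 to 92.5 ± 5.2 CPM), and ER chaperones rose in 18 of 20 (Hspa5 1860 ± 45 to 3950 ± 39). All 24 mitotic, 26 replication and 21 cholesterol genes fell, with Hmgcs1 from 690 ± 20 to 172 ± 1.1. Glycolysis genes fell in 18 of 20 and rose in 1 (Hk2 786 ± 1.5 to 440 ± 0.1). Camera gave adjusted p = 0.00017 for effector, 0.00022 for inhibitory, 5e-19 for ISR, 1.3e-06 for ER chaperones, 6e-09 for glycolysis and 8.4e-16 for each of mitotic, replication and cholesterol. In that order, adjusted p = 0.22, 0.045, 0.046, 0.22, 0.082, 0.013, 0.013 and 0.045 with an estimated correlation. Atp2a2 fell by a log2 change of 0.17 (adjusted p = 1.3e-05). All 6 tested mitochondrial mRNAs fell (camera adjusted p = 0.0087; adjusted p = 0.44 with an estimated correlation), as did 3 of 3 B cell and 3 of 3 fibroblast and endothelial markers. In all, 4382 genes were higher and 4352 lower, 1113 and 1193 by at least 2-fold. The balance turned to 4227 and 4498 with relative log expression scaling and to 3466 and 3824 with DESeq2.

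The interaction of TG with activation asked which TG effects differed between activated and resting T cells. Ifng (-6.21 ± 0.062) had a far smaller rise in activated cells. Xcl1 (-8.50 ± 0.089) went from 1110 ± 4.6 to 908 CPM there and from 2.37 ± 0.96 to 688 ± 16 in resting cells. Nr4a1 (-4.68), Pdcd1 (-1.49), Ccl1 (-7.70) and Lad1 (-7.75) also had negative differences, and Atp2a2 had -0.87 ± 0.05 (adjusted p = 7e-22). Sgk1 (4.01 ± 0.11) went from 12.1 to 48.7 CPM in activated and from 61.8 to 15.4 in resting cells. Klhl30 (4.12 ± 1.6), Sntb1 (3.72), Ret (3.66), Gzmb (1.06 ± 0.041), Ddit3 (1.21 ± 0.13) and Bcl2l11 (1.13) were positive as well. NF-kB genes were negative in 17 of 18 (camera adjusted p = 3e-12; adjusted p = 0.017 with an estimated correlation). Receptor and NFAT genes were negative in 18 of 25 and positive in 4 (2e-07; adjusted p = 0.11 with an estimated correlation). In all, 3588 differences were positive and 3383 negative, 950 and 865 by at least 2-fold, and the balance turned with relative log expression scaling (3428 and 3557) and DESeq2 (2556 and 2686).

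**Figure D4:**
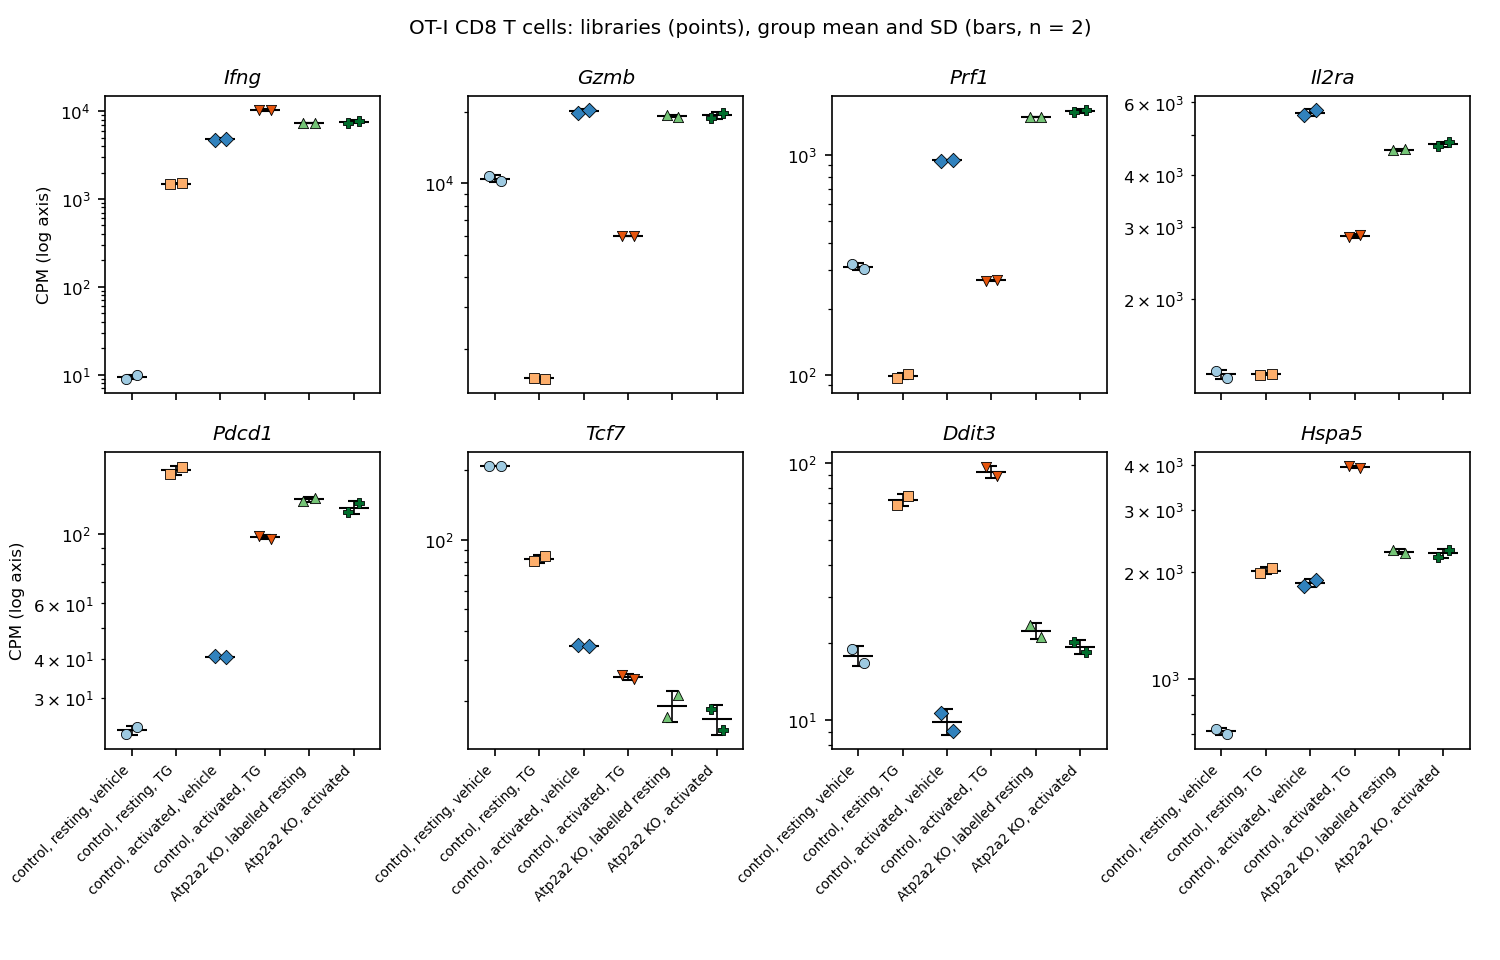
CPM of Ifng, Gzmb, Prf1, Il2ra, Pdcd1, Tcf7, Ddit3 and Hspa5 in the 6 T cell groups on log axes, with points for libraries and bars for mean and SD (n = 2). Gzmb was 20100 CPM in activated control, 6000 with TG and 19400 with Atp2a2 KO.

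The next question was how activated Atp2a2 KO T cells differed from activated controls. Itih5 rose from 1.6 ± 0.95 to 24 ± 0.3 CPM, Stard9 from 3.07 to 30.1 ± 6.6, Pglyrp1 from 1.95 to 17.2, Scml4 from 1.92 to 14.3, Synpo from 2.7 to 19.8 and Il5 from 3.44 ± 0.58 to 24.6 ± 1.3. S1pr1 fell from 28.8 ± 0.13 to 10.5 ± 1.1, Igfbp4 from 11 to 4.59, Il2 from 16 ± 0.32 to 6.96 ± 0.14, Rxra from 16.6 to 7.43, Gad2 from 20 to 8.93 and Iigp1 from 12.2 to 5.35. Ifng rose from 4790 ± 110 to 7590 ± 300 (0.67 ± 0.031, adjusted p = 1.2e-25), Prf1 from 948 ± 2.3 to 1590 ± 26, Gzmd from 457 ± 13 to 1240 ± 44 and Csf2 from 80.4 ± 0.67 to 211 ± 9.5. Gzmb was not called (19400 ± 610 against 20100 ± 370, adjusted p = 0.13), and Tnf fell from 114 ± 4.7 to 79.3 ± 3.3. Pdcd1 rose from 40.7 ± 0.066 to 121 ± 5.7 (1.56 ± 0.052, adjusted p = 6.7e-32), and Tcf7 fell from 34.6 ± 0.2 to 16.6 ± 2.5. Atp2a3 rose from 79.8 ± 1.4 to 123 ± 0.51, Orai1 from 26.8 ± 0.71 to 54.2 ± 1.3, and Bcl2l11 from 23.6 ± 0.43 to 60.2 ± 0.3. Ddit3 rose from 9.87 ± 1.1 to 19.3 ± 1.3, Trib3 from 27.3 ± 1.3 to 68.1 ± 1.4 and Hspa5 from 1860 ± 45 to 2260 ± 69.

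ISR genes rose in 32 of 36 and fell in 2 in activated Atp2a2 KO cells (camera adjusted p = 1.3e-24), inhibitory genes rose in 11 of 13 and fell in 2 (5.1e-08). All 24 mitotic (3.9e-21) and 26 replication genes (4.1e-17) fell, with Rrm2 from 228 ± 7.4 to 161 CPM. These calls held with an estimated correlation (adjusted p = 0.0077, 0.032, 0.0067 and 0.0072). Effector genes rose in 12 of 24 and fell in 7 (0.028; adjusted p = 0.4 with an estimated correlation), and interferon-stimulated genes fell in 14 of 24 and rose in 1 (16 and 1 alone; 2.2e-05; adjusted p = 0.081 with an estimated correlation). In all, 2357 genes were higher and 2629 lower of 13432, 350 and 64 by at least 2-fold. DESeq2 called 1474 higher and 1665 lower. Transcripts of most melanoma pigment genes were fewer in the KO libraries: Tyrp1 had 238 counts over the 8 control libraries and 1 over the 4 KO libraries, and Dct had 130 and 1. Pmel kept 26 counts over the 4 KO libraries against 132 over the 8 controls. In activated cells alone it had 17 counts with KO and 36 in the control, and was not called (adjusted p = 0.23). For other genes, a batch of handling or sequencing that follows genotype and the Atp2a2 KO cannot be told apart.

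The libraries labelled resting Atp2a2 KO were compared with resting control T cells. Il1a (22 ± 3 CPM), Il22 (19.5) and Rbpms2 (10.3) had no counts in the controls, at least 170-, 151- and 79.6-fold. Ccl9 rose from 0.126 to 148 ± 2.7 (counting interval of the ratio 393 to 5580), Lad1 from 0.0863 to 93.7 ± 0.77 (302 to 9020) and Inhba from 0.0402 to 43.2 ± 2.9 (180 to 39800). Ifit1bl1 fell from 16.6 to 0.0507, Cd7 from 35 ± 1.6 to 0.443, Cxcr3 from 47.8 ± 1.6 to 0.686 ± 0.25, Ret from 16 to 0.253, Rtp4 from 17.2 to 0.296 and Nod1 from 51.1 to 0.936. Ifng rose from 9.39 ± 0.55 to 7380 ± 35 (9.62 ± 0.052), Prf1 from 311 ± 11 to 1490 ± 3.2, Gzmb from 10500 ± 320 to 19200 ± 210, Il2ra from 1320 ± 34 to 4610 ± 29 and Hspa5 from 712 ± 18 to 2280 ± 36, and Tcf7 fell from 209 ± 0.45 to 19 ± 2.9. NF-kB genes rose in 16 of 18 and naive and memory genes fell in 18 of 21 with 2 up (camera adjusted p = 3.3e-09 and 3.8e-06; adjusted p = 0.018 for each with an estimated correlation). In all, 4524 genes were higher and 4819 lower, 1495 and 1901 by at least 2-fold.

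Activated and labelled resting Atp2a2 KO libraries were then compared directly, a comparison added after the data had been examined. Ifng (7590 ± 300 against 7380 ± 35 CPM, adjusted p = 0.68), Gzmb (19400 ± 610 against 19200 ± 210, adjusted p = 0.95) and Atp2a2 (adjusted p = 0.55) were not called. Ccl1 fell (log2 change -0.40, adjusted p = 3.2e-07), Arc from 11.6 to 7.31 and Btg2 from 102 to 78.6, while Bcar1 rose from 12.3 ± 2.3 to 18.3 ± 0.32. Amn1 (0.55), Aldoart1 (0.53) and Rasa4 (0.51) rose as well, and so did the mitochondrial mRNAs mt-Cytb (0.24), mt-Nd1 (0.23) and mt-Co1 (0.19), 3 of 6 tested (6 of 6 alone; camera adjusted p = 3.1e-18; adjusted p = 0.059 with an estimated correlation). In all, 63 genes were higher and 16 lower of 13432, 1 and 0 by at least 2-fold, and 1411 had an unadjusted p below 0.05. The count of 79 is unsteady: it was 15 to 191 when 1 library was left out, 27 with DESeq2 and 184 without a filter. The same step in control cells had 9990 calls. A chi-square per gene between 2 libraries was 1.978 to 3.928 for pairs with 1 library of each KO label. It was 3.092 between the 2 activated and 1.813 between the 2 labelled resting KO libraries. Pairs of resting and activated control libraries with vehicle had 161.4 to 186.6. The interaction of KO with activation was close to control activation with the sign reversed. Ifng had -8.96 ± 0.061, Atp2a2 -1.64 ± 0.05 (adjusted p = 5.9e-35), Tcf7 2.42, Hspa5 -1.40 and Gzmb -0.93, and 4515 differences were positive and 4256 negative, 2024 and 1591 by at least 2-fold (3635 and 3646 with DESeq2). NF-kB genes were negative in 18 of 18 and naive and memory genes positive in 19 of 21 with 2 negative (camera adjusted p = 2.9e-10 and 1.7e-05; adjusted p = 0.027 and 0.029 with an estimated correlation). Every result that uses the libraries labelled resting Atp2a2 KO depends on that label.

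TG and Atp2a2 KO were compared with each other in activated T cells. Ccn1 was 40.6 ± 1.8 CPM with TG and 1.12 ± 0.064 with KO, Fam171b 77.1 ± 3.2 and 2.91 ± 0.015, Cox6a2 14 ± 0.58 and 0.623, and Cd33 12.6 ± 0.9 and 0.951. Tgm2 was lower with TG (1.39 ± 0.45 against 72.3 ± 1.5), as were Epas1 (3.52 ± 0.53 against 160 ± 6.2), Tcrg-C1 (0.2 against 11.9) and Zfp683, which encodes HOBIT (0.0426 against 11.3 ± 1.4; counting interval of the ratio 8.9e-05 to 0.0198). Gzmb was 6000 ± 6.2 with TG and 19400 ± 610 with KO (-1.69), Prf1 270 ± 1.9 and 1590 ± 26 (-2.56), Ifng 10300 ± 130 and 7590 ± 300 (0.44) and Il2 30.3 ± 1.2 and 6.96 ± 0.14 (2.12). Ddit3 was 92.5 ± 5.2 and 19.3 ± 1.3 (2.25 ± 0.072), Hspa5 3950 ± 39 and 2260 ± 69 (0.81), and Bcl2l11 was not called (57.6 ± 0.3 and 60.2 ± 0.3, adjusted p = 0.34). ISR genes were higher with TG in 32 of 36 and lower in 2 (33 and 2 alone), cholesterol genes lower in 21 of 21 and effector genes lower in 18 of 24 and higher in 6. For these lists camera had adjusted p = 4.5e-17, 4.5e-17 and 6.6e-07, and in that order adjusted p = 0.064, 0.038 and 0.17 with an estimated correlation. In all, 4095 genes were higher with TG and 4035 lower, 742 and 1110 by at least 2-fold, against 3093 and 3352 with DESeq2. The split of Tyrp1 counts by genotype applies here too, so a batch cannot be told apart from the difference.

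Against the libraries labelled resting Atp2a2 KO, TG in resting control cells gave lower effector genes in 20 of 24 and higher in 4 (camera adjusted p = 2.2e-09; adjusted p = 0.15 with an estimated correlation). Il1a had no counts with TG and 22 ± 3 CPM with KO, at least 182-fold lower, and Serpinb9b was 0.838 ± 0.09 and 244 ± 4.7. Il22 was 0.0376 and 19.5 (counting interval of the ratio 5.2e-05 to 0.0115) and Il5 0.124 and 24.1 ± 0.71 (0.00102 to 0.0147). Fam81a had 10.4 ± 1.2 CPM with TG and no counts with KO, at least 69.6-fold, Tnfaip2 62.7 ± 0.7 and 0.149 (145 to 2060), Vipr2 23.3 and 0.0481 (84.4 to 18700) and Kcnh3 11.3 and 0.0507 (40.8 to 9090). Ifng was 1490 ± 14 and 7380 ± 35 (-2.31 ± 0.032), Gzmb 1500 ± 13 and 19200 ± 210 (-3.68) and Tcf7 82.7 ± 3.2 and 19 ± 2.9 (2.12). In all, 4756 genes were higher with TG and 4601 lower, 1648 and 1406 by at least 2-fold, against 3970 and 4049 with DESeq2. These libraries carry the doubtful resting label, and the genotype split of Tyrp1 means that a batch and the KO cannot be told apart here either.

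The changes with TG and with Atp2a2 KO in activated T cells, both against the same 2 control libraries, had Pearson r = 0.4 and Spearman rho = 0.476 across 13432 genes. 1535 genes were higher in both (769 if independent), 1988 lower in both (852), and 210 and 406 were called in opposite directions. In 20 simulations of groups that did not change, the shared controls alone gave a mean r of 0.456 with no overlap of calls. These simulated groups hold no real changes, so their r says little about the observed r, and the covariance was compared instead. The covariance was 0.205 against 0.0432 in the simulations, a difference of 0.162. For the labelled resting pair r was 0.603, and 2442 and 3048 genes were called in the same direction (1540 and 1700 if independent), with a simulated r of 0.493 and a covariance of 1.13 against 0.0595. Without the genes called in activation r was 0.308. A split of the controls would leave 1 library for each comparison and was not made, so part of the excess over independent calls can come from the shared controls.

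The last question was whether TG acted more strongly on melanoma than on T cells. The rise of Hspa5 was larger in melanoma by a log2 difference of 1.82 ± 0.04 against resting and 2.23 ± 0.04 against activated T cells, and of Herpud1 by 2.98 ± 0.058 and 2.65 ± 0.057. It was larger for Ddit3 by 2.71 ± 0.11 and 1.49 ± 0.12, for Trib3 by 2.83 ± 0.076 and 1.84 ± 0.082 and for Atf4 by 0.76 and 0.85. Mvd (3.72 ± 0.1 and 4.01 ± 0.095) and Fdps (3.05 and 2.44), both of cholesterol synthesis, rose in melanoma and fell in T cells. Bcl2l11 differed by -0.80 ± 0.19 and -1.93 ± 0.19, and Bbc3 by 1.37 against resting cells and -0.36 (adjusted p = 0.31) against activated cells. IRE1 and XBP1 targets were positive in 25 of 27 and negative in 1 in both comparisons (camera adjusted p = 1.3e-11 and 3e-17; adjusted p = 0.023 and 0.0085 with an estimated correlation). ER-associated degradation genes were positive in 14 of 20 with 0 negative (14 and 1 alone) and 13 with 1 negative (adjusted p = 1.5e-06 and 7.1e-08; 0.023 and 0.014 with an estimated correlation). ISR genes were positive in 17 of 39 and negative in 13 against resting cells (18 and 13 alone; adjusted p = 0.16) and positive in 22 and negative in 8 against activated cells (23 and 8 alone; adjusted p = 1.4e-05; adjusted p = 0.15 with an estimated correlation).

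Cholesterol genes were positive in 21 of 21 against resting and 20 of 21 against activated T cells (camera adjusted p = 1.3e-15 and 3e-17; adjusted p = 0.013 and 0.005 with an estimated correlation). Pro-apoptotic genes were positive in 4 and negative in 4 of 17 against resting cells (adjusted p = 0.92) and positive in 1 and negative in 6 against activated cells (adjusted p = 0.17). In all, 3496 differences were positive and 3532 negative of 14824 against resting cells (1287 and 1226 by at least 2-fold), and 3205 and 3229 against activated cells (939 and 997). The log2 changes with TG in melanoma and in T cells had r = 0.352 (rho 0.426) for resting and 0.437 (0.482) for activated cells across 11195 genes, against r = 0.618 (0.574) between resting and activated T cells. With no filter on low counts these r were 0.17, 0.167 and 0.295. TG was given at 50 ng/mL for 8 hours to both cell types, and a difference in drug uptake would be counted here as a difference in response.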

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

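The differences between effects in this part come from comparisons planned before the data were examined. Tests of explanations were chosen only after the result was seen, except that of melanoma transcript carried into T cell libraries.

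Large numbers of differences between effects drew attention. By the interaction test, the TG effect differed between Ccdc101 KO and control melanoma for 1644 genes, between activated and resting T cells for 6971 genes, between melanoma and resting T cells for 7028 genes and between melanoma and activated T cells for 6434 genes. The effect of activation differed between Atp2a2 KO and control T cells for 8771 genes.

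The 8771 differences come with libraries labelled resting Atp2a2 KO that hold activation genes at activated levels. Activated and labelled resting KO libraries differed in 79 genes (15 to 191 with 1 library left out), against 9990 in control cells. A wrong label or activated cells in the resting wells would give this, and so would an activated state of KO cells without anti-CD3; these cannot be told apart. Swapped resting and activated KO labels cannot be tested by such counts. The libraries labelled activated Atp2a2 KO differed from resting controls in 9589 genes and from activated controls in 4986. Those labelled resting differed in 9343 and 4237, so exchanged labels would give much the same counts. Whether activated control libraries carry the resting KO label cannot be decided by the 4237 genes either. A batch that follows genotype could also set such libraries apart from the activated controls.

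The 7028 and 6434 differences between cell types include Atp2a3, which rose in melanoma from 0.0375 to 31.2 CPM. RNA of T cells in the melanoma libraries would raise it too, since Atp2a3 is a T cell gene. The summed level of 18 T cell genes in TG-treated melanoma was 6.97 CPM, whereas 468 would be needed, so this source is argued against.

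Transcripts of melanoma genes in control T cells could be carry-over between libraries or expression by the T cells. The test took 47 genes with at least 100 CPM in melanoma and at most 2 counts in the KO libraries. The rank correlation of their counts in control T cells with their level in melanoma was 0.652. Carry-over would give such an order, and expression of single genes by control T cells alone would not be expected to. Genes that T cells of both genotypes express were left out by the choice on KO counts, so the test does not bear on them. A check added after took 15 pigment genes with at least 100 CPM in melanoma. 13 of them had a lower share of their melanoma level in the 4 KO libraries than in the 8 control libraries. Tyrp1, for example, had 1 count against 238. The counts of Tyrp1, Dct, Pmel and Mlana were seen first, so these were left out of the 47 genes but are among the 13. Met and Mitf are also among the 13. Of the 15 genes 5 kept more than 2 counts in the KO libraries. Rab27a (13872 against 24704 counts) is expressed by T cells, and Met and Mitf, at 0.199% and 0.295% of their melanoma level in controls, lay far above Tyrp1 at 0.0369%, so these 3 do not bear on carry-over. Pmel (26 against 132) and Slc24a5 (4 against 7) leave the split incomplete. A KO in T cells would not remove carried-over RNA, so a batch that follows genotype is the open source of the split, and its effect on other genes and that of the KO cannot be told apart.

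The 1644 and 6971 differences among melanoma and among T cell groups were not traced to an artifact. Unequal starting levels, as for Ifng at 9.39 CPM in resting and 4790 in activated cells, change how far a log2 value can move, and a true dependence of the TG response on genotype or activation would also give them.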

How the results depend on the processing

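All settings in this part were fixed before the data were examined except the fits without the libraries labelled resting Atp2a2 KO and the comparison of activated with labelled resting KO. No named gene that was called changed sign with DESeq2, relative log expression scaling, the replicate term or only the compared groups. Signs of named genes were not compared without a filter, with the strict filter or with a library left out. No list called by both camera and fry changed direction, and no correlation changed sign. The balance of higher and lower calls turned in 7 comparisons. With relative log expression scaling it became 4227 and 4498 for TG in activated T cells, 3428 and 3557 for its interaction with activation, and 3977 and 4126 for TG against KO in activated cells. With DESeq2 these were 3466 and 3824, 2556 and 2686, and 3093 and 3352. DESeq2 alone turned TG in KO melanoma (3634 and 3625), Ccdc101 KO with TG, the KO interaction with activation (3635 and 3646) and TG against labelled resting KO (3970 and 4049). DESeq2 called 1508 genes for Ccdc101 KO with vehicle (561 higher, 947 lower; 1500 shared with edgeR), 2110 with TG (1032, 1078; 2076), 664 for the melanoma interaction (442, 222; 655), 3139 for activated Atp2a2 KO (1474, 1665; 3129) and 27 for activated against labelled resting KO (24, 3; 23). Without a filter the last had 184 calls, 77 shared. Of 2318 tests of a named gene in a comparison, DESeq2 lost 179 calls and gained 1. Of 504 list tests the estimated correlation lost 203 calls, while fry gained 165 and lost 7.

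Pearson r between TG and KO in the labelled resting pair was 0.514 with no filter, 0.628 with the strict filter, 0.668 with only the compared groups, 0.308 with activation genes left out and 0.632 for genes above the median level. For the activated pair it was 0.47 with only the compared groups and 0.549 above the median. With no filter, the strict filter and only the compared groups it was 0.393, 0.959 and 0.934 for TG in control and KO melanoma, 0.17, 0.412 and 0.371 for melanoma and resting T cells, 0.167, 0.512 and 0.463 for melanoma and activated T cells, and 0.295, 0.692 and 0.677 for resting and activated T cells.

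Without the libraries labelled resting Atp2a2 KO, calls (and shared calls) were 9283 (9223) for TG in resting cells, 8729 (8700) in activated cells, 6937 (6881) for their interaction, 9970 (9947) for activation, 4947 (4914) for activated KO, 8108 (8076) for TG against KO, and 7014 (6958) and 6415 (6388) for melanoma against resting and activated T cells.

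Leaving out each library in turn leaves an arm of 1 library, taken to vary like the other groups. Calls then ranged from 8328 to 8465 (TG in control melanoma), 7899 to 8129 (in KO), 2332 to 2537 (KO, vehicle), 2615 to 3408 (KO, TG), 1090 to 1565 (interaction), 8416 to 8744 (TG in resting T cells), 7866 to 8116 (activated), 6260 to 6528 (their interaction), 9330 to 9530 (activation), 8646 to 8830 (labelled resting KO), 3675 to 4548 (activated KO), 8165 to 8556 (KO interaction), 8534 to 8803 and 7104 to 7688 (TG against KO), 6486 to 6675 and 5833 to 6069 (melanoma against T cells) and 15 to 191 (activated against labelled resting KO). The range of r was 0.578 to 0.635 and 0.344 to 0.508 for TG and KO (labelled resting, activated), 0.892 to 0.902, 0.325 to 0.347, 0.408 to 0.42 and 0.582 to 0.616 for the others in the order above.

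A term for replicate number gave 8959, 8748, 3133, 3856, 1541, 9264, 8697, 6917, 9955, 9313, 4900, 8716, 9324, 8056, 6984 and 6395 calls in the order of the ranges, and 65 for activated against labelled resting KO. Replicate numbers do not pair the groups: of 45 pairs of groups, r of the replicate differences ran from -0.2 to 0.204. While 5 were above 0.1, others were clearly negative, such as -0.19 and -0.172. Replicate differences shared with opposite signs are not taken up by a term for replicate number.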

Other observations

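The tests of label and of T cell RNA used in this part were chosen only after the result was seen, and the carry-over test before.

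Further genes changed with TG, although their lists were not called in control melanoma. In control melanoma the antioxidant genes Hmox1 (47.4 ± 1.9 to 642 ± 16 CPM) and Slc7a11 (26.7 ± 0.64 to 584 ± 37) rose, and NRF2 targets as a list rose in 8 and fell in 5 of 14 (camera adjusted p = 0.18). The secreted factor gene Vegfa rose from 34.8 ± 0.1 to 213 ± 0.098, and secreted cytokine genes rose in 5 and fell in 1 of 10 (adjusted p = 0.14). Relb rose from 6.24 ± 0.4 to 43.8 ± 1.9, and NF-kB genes rose in 5 and fell in 1 of 10 (adjusted p = 0.083). Cholesterol genes rose in 13 and fell in 6 of 21 (adjusted p = 0.11), interferon-stimulated genes rose in 9 and fell in 6 of 17 (adjusted p = 0.75), MHC class I genes rose in 5 and fell in 2 of 9 (adjusted p = 0.44), and calcium-handling genes rose in 10 and fell in 10 of 23 (adjusted p = 0.7). Ribosomal protein genes rose in 14 and fell in 2 of 25 (adjusted p = 0.078), SAGA subunits rose in 9 and fell in 6 of 23 (adjusted p = 0.76), and mitochondrial mRNAs rose in 1 and fell in 2 of 6 (adjusted p = 0.7). These counts were the same when adjusted over the list alone.

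In activated T cells TG raised 23 of 25 ribosomal protein genes (adjusted p = 6.9e-06; adjusted p = 0.3 with an estimated correlation). T cell identity genes rose in 12 and fell in 5 of 18 (adjusted p = 0.008; adjusted p = 0.22 with an estimated correlation), and CD4 and NK cell markers rose in 4 and fell in 2 of 6 (adjusted p = 0.42). Of 6 myeloid markers 0 rose and 0 fell (adjusted p = 0.88). Survival genes rose in 6 and fell in 4 of 11, with a median log2 change of 0.21 although the test pointed down (adjusted p = 0.88). In activated Atp2a2 KO cells heat shock genes fell in 8 of 13 (adjusted p = 1.8e-06; adjusted p = 0.081 with an estimated correlation). These counts were the same when adjusted over the list alone.

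The Atp2a2 KO libraries looked activated under both labels, with 79 genes between them (15 to 191 with 1 library left out). This is consistent with cells that were activated before or without anti-CD3, and equally with a wrong label; the 2 cannot be told apart. Swapped labels cannot be tested by such counts, since both lay far from resting controls (9589 genes for activated KO, 9343 for labelled resting KO). The labelled resting KO libraries differed from activated controls in 4237 genes. This does not decide whether they are activated control libraries, since a batch that follows genotype could also give such differences.

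TG-treated melanoma expressed Atp2a3, and 6.97 CPM of summed T cell genes argues against T cell RNA as the source. A response of the melanoma cells to the blocked pump would give the same rise, and in Ccdc101 KO cells Atp2a3 also rose, from 0.258 to 36.4 CPM. Neither the protein nor its activity was measured.

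Over 47 genes with at most 2 counts in the KO libraries, melanoma transcripts in control T cells followed their melanoma level (rho = 0.652). Carry-over at a small share would give this, but the choice left out genes that both T cell genotypes express. Of the genes called lower in Atp2a2 KO, 2 of 4819 (labelled resting) and 3 of 2629 (activated) could be mostly carry-over by their level. A batch that follows genotype and the KO cannot be told apart for the remaining genes.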
